A study of Mus musculus with 8 samples.

How the data were processed

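Total RNA from the dorsal dentate gyrus of the hippocampus of male mice, 8 to 12 weeks old, was compared between wild-type animals (WT) and animals lacking the T-type calcium channel Cav3.1 (Cav3.1 KO). Cav3.1 is the pore-forming subunit encoded by Cacna1g. Each group had 4 arrays, and the labels give the strain of both groups as C57BL/6J. Per the labels' protocols, the RNA was purified on columns, amplified to aminoallyl RNA, coupled to the dye Cy5 and hybridised to a TORAY chip with a single colour. The labels speak of brain slices of the mice and do not state that each array came from a separate animal, so the p-values measure the spread between these samples, which may in part be technical.

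The scanner output of each array gives a median spot intensity, not normalised, per the file headers, together with flags at 3 scan gains. How the gains were merged into that intensity is not given in the sources used here. A second intensity under a background heading followed the brightness of its own spot on every array, blank positions included, with correlations of the logarithms of 0.994 to 0.996. It was therefore not taken as a local background and was used only for this check. The value table of the series, as deposited by the authors, holds a linear intensity for each probe and array with a median of 25 on every array. Set against the scanner values, it was a straight line on each array, with 0 at a spot intensity close to the mean of that array's blank spots (52.8 against 53.0 on WT replicate 1), so it was a blank-subtracted intensity scaled to 1 median, without centring of genes and with dim probes left empty. The table's scale is thus known from the values, and the name of the authors' normalisation is not given in the sources used here.

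Each array carried 27456 spots, of which 2736 were blank, 1102 held no probe, 96 were negative controls and 48 were positive controls. The remaining spots held 23473 probes, 1 of them spotted more than once and averaged. The planned background correction presupposed a local background. Because none could be used, normexp with an offset of 50 was fitted to the spot intensities alone, control spots included, and the corrected log2 intensities of the probes were quantile normalised. A probe counted as detected on an array if its intensity lay above the 95th percentile of that array's blank spots. Probes detected on at least 4 of the 8 arrays were tested. This left out 2239 dim probes, and a further 84 were left out because a spot was marked as not good at any gain on any array. The test therefore covered 21150 probes. Of all probes on the array, 20690 had 1 gene symbol in the platform annotation, 0 had several and 2783 had none. The gene identifiers of 20556 probes matched the RefSeq gene table of GRCm38.p6, which changed 0 symbols. That table served only for names and for which genes neighbour each other, since the sources used here name no genome build for the array.

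The number of arrays limits the precision. Between 85.4% and 93.0% of probes were detected on an array, and the median probe was 1.44 to 1.63 times as bright as the mean blank spot. With the offset of 50, the log2 differences understate the change of dim genes. The difference after plain subtraction of the mean blank spot is given beside some of them.

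Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means only), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05 on the adjusted p. For single values, exact two-sided permutation tests over all 70 arrangements were used, and their smallest possible p was 0.0286. A set of 40 gene lists was tested with camera, at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Each gene was represented by the probe with the highest mean over all arrays. Genes within 10 Mb of Cacna1g were compared with the other genes by Fisher's exact test. On simulated data with 21150 probes for this comparison, 26 of 50 probes changed by 0.25 on the log2 scale were recovered, 44 of 50 at 0.5, 48 of 50 at 1 and 49 of 50 at 2, with 10 false calls. With nothing changed there were 0 calls. The simulated noise was independent between probes and held no differences of array run or tissue content. These counts are therefore not the power or error rate of the real comparison.

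The gene lists, the tests between the groups and the naming rule were fixed before the data were examined, but the background correction was replaced as described, and some tests of explanations were chosen after the results were seen. The rule named Cacna1g, Cacna1h and Cacna1i, then the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with an established symbol and no overlap between the groups, and up to 4 members of a list with the smallest p. Predicted genes and probes without a symbol were counted, and those named nevertheless are said to have been chosen after their values were seen. The files of WT replicate 3 and Cav3.1 KO replicate 4 carry later array numbers than the other 6, and this array run was treated as a batch. Within each run the WT arrays carry the lower numbers: 44, 45 and 47 against 49, 50 and 51, then 61 against 62. Array order thus followed the groups, and neither the run as a block nor the first run alone can remove it. Alternatives covered the background correction, the normalisation, the value table of the series, the filter on dim probes, array weights, the variance model, the array run, the replicate number as a block, the threshold, a Student test without moderation, the list test and the removal of each array in turn. A normexp offset of 10, the retention of flagged probes and the removal of Cav3.1 KO replicates 2 and 3 together were added after the data were seen. No column of per-sample values was left unused.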

Results

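Gene expression in the dorsal dentate gyrus was measured on 8 single-colour arrays, 4 from WT mice and 4 from mice without the T-type calcium channel Cav3.1. The arrays were of similar brightness, with mean blank-spot intensities between 53.0 and 63.4 and median probe intensities between 81.0 and 94.3. Within the first run the blank means did not overlap, at 53.0 to 55.4 in WT and 56.2 to 63.4 in Cav3.1 KO. The lowest shares of detected probes, 87.0% and 85.4%, were on WT replicate 3 and Cav3.1 KO replicate 4, the 2 arrays of the later run. Normalised values of any 2 arrays correlated across probes with r between 0.991 and 0.997. Values are normalised log2 intensities, and differences are Cav3.1 KO minus WT.

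The targeted gene was examined first. The probe for Cacna1g, which encodes Cav3.1, gave 6.54 ± 0.0814 (SD, n = 4) in WT and 6.46 ± 0.0716 (SD, n = 4) in Cav3.1 KO. The difference of -0.08 (SE 0.0508, 95% interval -0.199 to 0.035) did not pass the test, with an exact permutation p of 0.171 and a limma adjusted p of 0.816, and the values of the groups overlapped. The probe was dim, and the difference was -0.195 after subtraction of blank spots and -0.243 in the value table of the series, neither past the threshold. The probe was detected on all 8 arrays, at a mean spot intensity of 97.1 in WT and 94.5 in Cav3.1 KO against mean blank spots of 55.4 and 60. Where this probe lies relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part would not report the deletion, so the measurement does not check the genotype. The other T-type channel genes, Cacna1h (encoding Cav3.2) and Cacna1i (encoding Cav3.3), did not pass the test either. Cacna1h differed by -0.07 (SE 0.0768, adjusted p 0.962). Cacna1i, whose spots were close to the blank level at 59.4 in WT and 63.1 in Cav3.1 KO, differed by -0.02 (SE 0.0249, adjusted p 0.976).

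**Figure D1:**
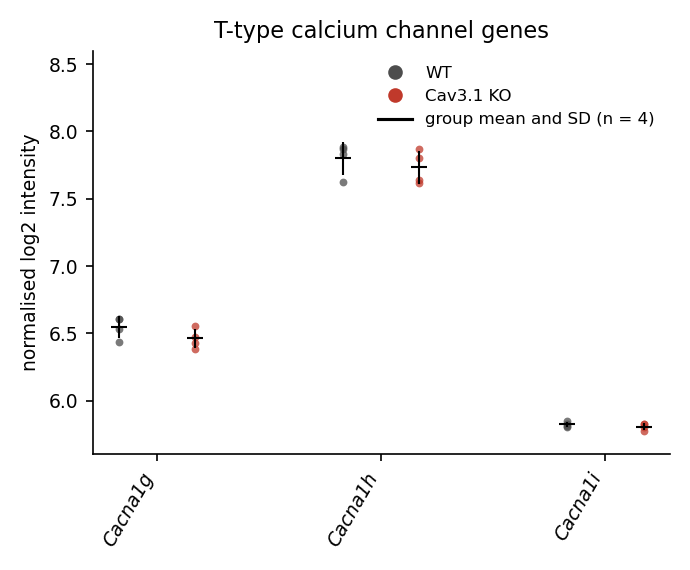
Normalised log2 intensity (vertical axis) of the probes for Cacna1g, Cacna1h and Cacna1i on each array, WT in grey and Cav3.1 KO in red, with the mean and SD of 4 arrays. For Cacna1g the groups overlap, with means of 6.54 in WT and 6.46 in Cav3.1 KO.

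The question of the series was how the dentate gyrus transcriptome differs without Cav3.1. The changes were few and, on the normalised scale, mostly modest. The strongest named rises included stress- and hormone-responsive genes such as Sgk1, Nfkbia, Tsc22d3 and Cdkn1a, together with the glucose transporter gene Slc2a1 and the GABA-A receptor subunit gene Gabra2. Among the strongest falls were the chemokine gene Ccl21d, the endothelial tight junction gene Cldn5 and the granule cell gene C1ql2. Of 21150 probes, 61 passed the threshold, 42 of them higher and 19 lower in Cav3.1 KO, with a median size of 0.40 on the log2 scale. Of the 61, 19 differed by more than 1.5-fold. Both sizes are on the normalised scale, which understates dim genes. After subtraction of the blank level all 61 differences were larger. The gain was small for the bright Gjb6 (0.40 against 0.38) and large for the dim Cdkn1a (2.23 against 0.86). All 61 separated the groups with no overlap, which their selection by a small p makes nearly certain. Over all probes tested, 4.95% separated the groups, where chance gives 2.86%. Among the 61 were 53 probes for established genes, 3 for predicted genes and 5 without a symbol. Before adjustment, 1713 probes had a p under 0.05, where 1057.5 would be expected by chance. Between the array runs, with genotype in the model, 1848 had a p under 0.05 and 3 passed after adjustment. The number of calls was 44 with the array run as a block and 7 within the first run of 3 against 3 arrays, while the later run held 1 array of each group. It was 16 without WT replicate 4, 26 without WT replicate 3, 29 without Cav3.1 KO replicate 2, 33 without Cav3.1 KO replicate 3, 34 without Cav3.1 KO replicate 4 and 37 without WT replicate 1. Markers of thalamus and habenula were highest on Cav3.1 KO replicates 2 and 3, and with both of these arrays left out 17 probes were called. Of the 24 named genes, 7 then passed, namely Gabra2, Slc2a1, Cdkn1a, Tsc22d3, Fam177a2, Ccl21d and Rasl10a. That comparison had 2 Cav3.1 KO arrays. All 24 kept their direction, which their choice for no overlap made certain. The differences were 1.36 for Sgk1, 0.91 for Arrdc2 and -0.59 for C1ql2, against 1.24, 0.99 and -0.57 with all arrays. Leaving out both arrays did not balance tissue content between the groups. The mean of choroid plexus markers then differed by -0.78 and that of ependymal markers by -0.314, against -0.255 and -0.0317 with all arrays.

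On the normalised scale, the largest rise among named genes was that of Sgk1, the serum- and glucocorticoid-regulated kinase, from 8.36 ± 0.239 (SD, n = 4) in WT to 9.60 ± 0.189 (SD, n = 4) in Cav3.1 KO, a difference of 1.24 (SE 0.133, 2.36-fold, adjusted p 0.0129). Polr3e, a subunit of RNA polymerase III, rose by 1.03 (SE 0.114, adjusted p 0.0152) and the arrestin-domain gene Arrdc2 by 0.99 (SE 0.0925, adjusted p 0.00663). Gabra2, the alpha-2 subunit of the GABA-A receptor, rose from 8.16 ± 0.0818 to 9.08 ± 0.183, and Slc2a1, which encodes the glucose transporter GLUT1, from 8.31 ± 0.12 to 9.22 ± 0.0874 (SD, n = 4), with adjusted p-values of 0.00779 and 0.00191. Nfkbia, the inhibitor of NF-kappa-B, rose by 0.91 (SE 0.0924), Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, by 0.84 (SE 0.083), and Ccn2, connective tissue growth factor, by 0.82 (SE 0.0761). The cell-cycle inhibitor gene Cdkn1a rose by 0.86 (SE 0.0579, adjusted p 0.00127). Its probe was dim in WT, and after plain subtraction of the blank level the difference was 2.23, above the 1.39 of Sgk1. For Ccn2 and Plekhf1, which rose by 0.61 (SE 0.0672), the blank-subtracted differences were 1.71, also above that of Sgk1, and 1.22. Fam177a2 rose by 0.71 (SE 0.0455) and Ctla2b by 0.70 (SE 0.0838), and both have a closely related gene that their probes may also detect. All 12 kept their direction whichever array was left out, which their choice for no overlap made certain, but some lost the call. Without WT replicate 4 these were Sgk1, Nfkbia and Tsc22d3 (adjusted p 0.055 each), Polr3e and Plekhf1 (0.0769 each) and Ctla2b (0.0823). Without WT replicate 3 they were Sgk1 (0.0535), Polr3e (0.0513), Plekhf1 (0.0755) and Ctla2b (0.0782). Plekhf1 and Ctla2b were also lost without Cav3.1 KO replicate 2 (0.0604 and 0.0692) or 3 (0.0556 and 0.0752), and Ctla2b without Cav3.1 KO replicate 1 (0.055).

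Ccl21d, a copy of the gene for the lymphoid chemokine CCL21, showed the largest fall among established genes on the normalised scale, from 8.998 ± 0.0538 (SD, n = 4) in WT to 7.97 ± 0.0591 (SD, n = 4) in Cav3.1 KO, a difference of -1.03 (SE 0.0399, adjusted p 3.03e-05). The mouse genome carries several near-identical copies of this gene, and the probe may report any of them. The reference places it on chromosome 4, as it does the predicted genes Gm7819 and Gm1987, named after their values were seen, which fell by 2.70 (SE 0.0941) and 1.38 (SE 0.0455). Tmem254c fell by 0.88 (SE 0.123, adjusted p 0.0422), and its probe may also report the copies Tmem254a and Tmem254b. After subtraction of the blank level it fell by 1.69, more than the 1.22 by which Ccl21d fell. Cldn5, the claudin of endothelial tight junctions, fell from 9.71 ± 0.0958 to 8.92 ± 0.186 (SD, n = 4), with an adjusted p of 0.0182. The Ras-like gene Rasl10a fell by 0.68 (SE 0.0398, adjusted p 0.000605), and Bok, a member of the BCL-2 family, fell by 0.65 (SE 0.0593, adjusted p 0.0065). C1ql2, a secreted C1q-like protein of mossy fibre synapses, fell by 0.57 (SE 0.0509, adjusted p 0.0065). The remaining falls were smaller and closer to the threshold, with adjusted p-values from 0.0406 to 0.049. Tssc4 fell by 0.39, the endocytic recycling gene Ehd1 by 0.38, the glutathione-degrading enzyme gene Chac1 by 0.38, the thrombospondin gene Thbs4 by 0.36, and the glypican gene Gpc4 and the F-box gene Fbxo22 by 0.34 each. The calls of these 6 genes and of Tmem254c depended on single arrays. Without WT replicate 4 their adjusted p-values ran from 0.0565 to 0.174 and without WT replicate 3 from 0.123 to 0.181, and each of the other 6 arrays, when left out, also ended between 3 and 7 of these calls. With the array run as a block 5 of the 7 were lost, Tmem254c (0.0886), Tssc4 (0.0874), Chac1 (0.0935), Gpc4 (0.0874) and Fbxo22 (0.0699). The call of Cldn5 was lost without WT replicate 1 (0.0652), WT replicate 3 (0.0836), WT replicate 4 (0.0847), Cav3.1 KO replicate 2 (0.0692) or Cav3.1 KO replicate 3 (0.0556).

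**Figure D2:**
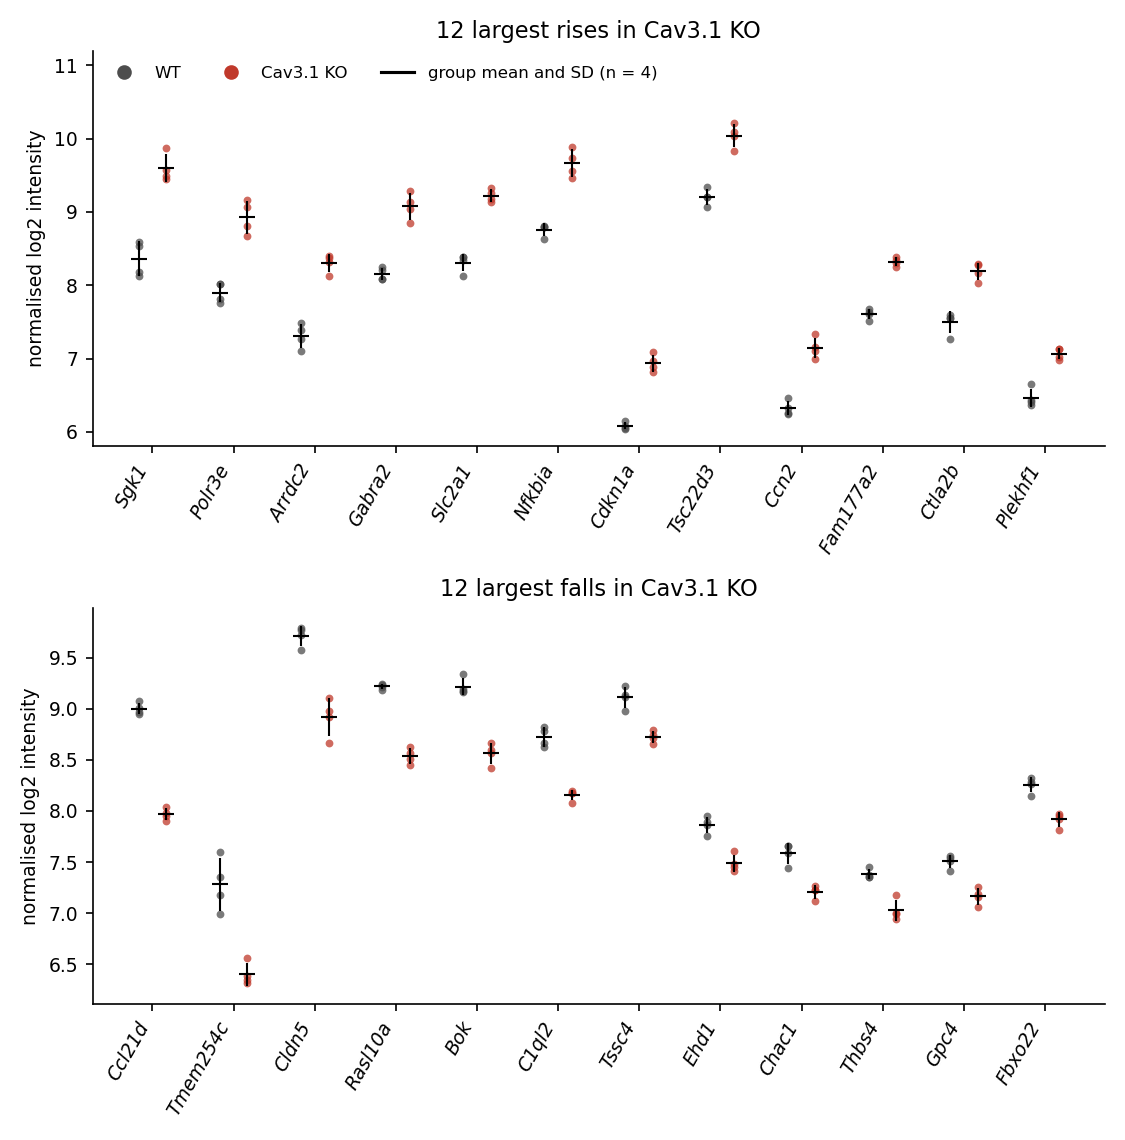
Normalised log2 intensity (vertical axis) on each array for the 12 genes with the largest rise (top) and the 12 with the largest fall (bottom), WT in grey and Cav3.1 KO in red, with the mean and SD of 4 arrays. The groups do not overlap for any of these genes, and the differences run from 1.24 for Sgk1 to -1.03 for Ccl21d.

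Glucocorticoid-responsive genes were higher in Cav3.1 KO as a group. Of 19 measured members, 18 were higher, 5 rose over all genes tested and 12 rose when adjusted over the list alone. Sgk1, Nfkbia, Cdkn1a and Tsc22d3 had the values given above, and the fifth, the hypoxia-inducible factor subunit Hif3a, named after its values were seen, rose by 0.19 (SE 0.0262). The median difference of the members was 0.153 and the mean 0.37, so the largest rises carried much of the mean. The list was not tested without them. The mean over the list was 7.71 ± 0.0312 (SD, n = 4) in WT and 8.08 ± 0.0298 (SD, n = 4) in Cav3.1 KO, with an exact permutation p of 0.0286, the smallest that 4 against 4 allows. Of the 40 lists 4 reached that p, the others being immediate early genes, neocortex markers and transcripts that vary between strains. The list differed from the other genes by camera with an adjusted p of 3.35e-17, and with adjusted p = 0.00287 with an estimated correlation, the only list called that way. The difference in the mean was 0.37 both without the array run as a block and with it (SE 0.0185). The block could not change it, because each run held as many WT as Cav3.1 KO arrays. The difference was 0.373 within the first run and 0.36 between the 2 later arrays. Fkbp5, a co-chaperone of the glucocorticoid receptor named after its values were seen, differed by 0.15 (SE 0.15, adjusted p 0.943).

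Immediate early genes, which are transcribed within minutes of a stimulus, were also higher as a group by camera (adjusted p 3.29e-06), but the call was lost with an estimated correlation (adjusted p = 0.169 with an estimated correlation). Of 34 measured members, 26 were higher and 8 lower. Over all genes 2 rose, Maff by 0.31 (SE 0.0365) and the antiproliferative gene Btg2 by 0.41 (SE 0.0476), both with an adjusted p of 0.0184. Adjusted over the list alone, 10 rose and 1, Bdnf, fell, with a difference of -0.51 (SE 0.12) and an adjusted p over all genes of 0.207. Gadd45g differed by 0.76 (SE 0.119, adjusted p 0.0609) and the transcription factor gene Klf4 by 1.15 (SE 0.182, adjusted p 0.0639), neither past the threshold over all genes. The neuronal activity markers Arc and Egr1, named after their values were seen, differed by 0.04 (SE 0.315) and -0.24 (SE 0.151). The list mean was higher by 0.18 over all arrays, which the array run as a block could not change. It was higher by 0.155 within the first run and by 0.267 between the later arrays. A single gene belonged to both of these lists, and without it the immediate early list had a camera p of 3.39e-07, and an unadjusted p = 0.0144 with an estimated correlation.

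**Figure D3:**
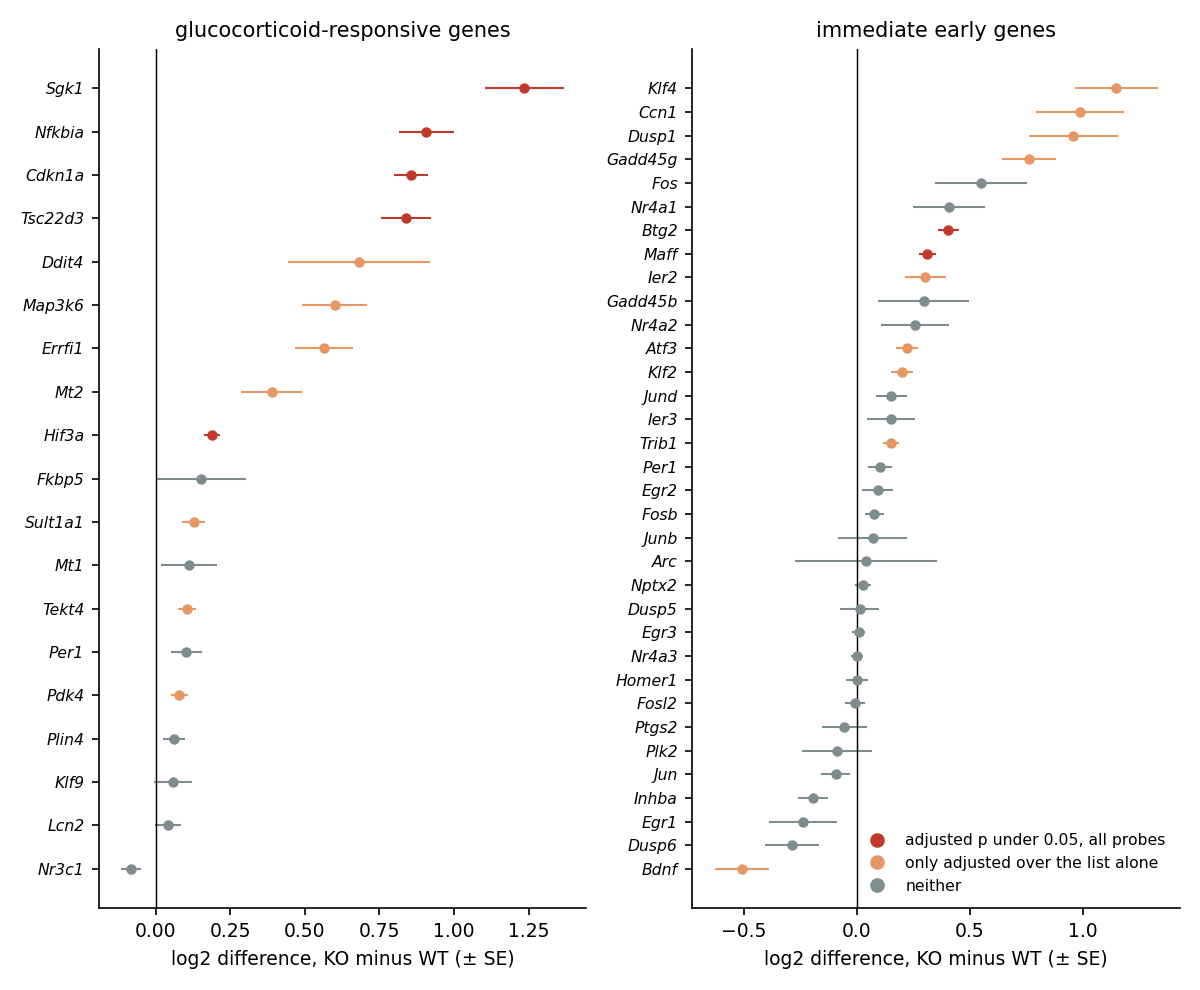
Log2 difference between Cav3.1 KO and WT (horizontal axis, with its SE) for the measured members of the glucocorticoid-responsive (left) and immediate early (right) lists, coloured by whether the adjusted p was under 0.05 over all probes, over the list alone, or neither. Of the 19 genes on the left 18 lie above 0, and Sgk1 at 1.24 lies farthest to the right.

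Markers of mature dentate granule neurons, the principal cells of the tissue, ranked lower in Cav3.1 KO by camera (adjusted p 0.0011), a call that was lost with an estimated correlation (adjusted p = 0.169 with an estimated correlation). The estimate for this list was 0.0189, near the preset 0.01, so correlation between its genes was not shown to be what undid the call. By fry, which tests the list against no change and not against other genes, it was lower with an adjusted p of 0.0286, while the exact permutation p of the list mean was 0.0857. Of 23 measured members 15 were lower. Over all genes 1 fell, C1ql2, and 4 fell adjusted over the list alone. The members after C1ql2 were Plk5 (-0.19, SE 0.0328), the cation channel gene Trpc6 (-0.57, SE 0.106) and Lct (-0.25, SE 0.0616), with adjusted p-values over all genes of 0.082, 0.104 and 0.231. The list mean differed by -0.077 over all arrays, which the array run as a block could not change. It differed by -0.105 within the first run, but by 0.00576 between the 2 later arrays. The thalamus and habenula list mean was 7.45 and 7.445 on Cav3.1 KO replicates 2 and 3, against 6.843 and 6.769 on replicates 1 and 4. Without replicates 2 and 3 the granule neuron list mean differed by -0.0649, with a camera adjusted p of 0.0267.

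Markers of microglia and macrophages were lower in Cav3.1 KO for 21 of 21 measured genes (camera adjusted p 6.88e-05), a call that was lost with an estimated correlation (adjusted p = 0.518 with an estimated correlation). By fry the adjusted p was 0.261 for a change one way. Of these genes 0 passed over all genes by limma and 1, Fcrls, fell adjusted over the list alone. The differences were -0.22 (SE 0.0498) for Fcrls and -0.34 (SE 0.0992) for the purinergic receptor gene P2ry12. The list mean was 7.83 ± 0.101 (SD, n = 4) in WT and 7.72 ± 0.0489 (SD, n = 4) in Cav3.1 KO (exact permutation p 0.114). The other lists that ranked lower by camera also lost the call with an estimated correlation. For heat shock and unfolded protein response genes, 22 of 27 were lower, Chac1 fell, and the adjusted p was 0.00502 and, with an estimated correlation, adjusted p = 0.675. For cytosolic ribosomal proteins, 43 of 58 were lower, 0 passed over all genes, and the adjusted p was 0.0122 and, with an estimated correlation, adjusted p = 0.737. Among postsynaptic scaffolds, 18 of 24 were lower, with Homer2 at -0.32 (SE 0.0675) and Shank3 at -0.16 (SE 0.0383), and the adjusted p was 0.0127 and, with an estimated correlation, adjusted p = 0.518. This list's mean also had opposite signs within the first run (-0.0995) and between the later arrays (0.0378). Meningeal fibroblast markers were lower for 15 of 19, with an adjusted p of 0.0127 and, with an estimated correlation, adjusted p = 0.737. The last 4 of these lists each lost the camera call without at least 1 array, with adjusted p-values of up to 0.203, 0.248, 0.107 and 0.318 in the order given. With Cav3.1 KO replicates 2 and 3 both left out, the ribosomal and postsynaptic lists had adjusted p-values of 0.0796 and 0.521. As many as 8 lists were also called in other divisions of the arrays.

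The other 32 of the 40 lists were not called by camera, and the adjusted p-values of lists that follow are camera's unless fry is named. By fry, which tests a list against no change, 4 of the 40 lists were called for a change one way and 14 for a change in either direction. Among the 14 were CA3 pyramidal neuron markers (fry adjusted p 4.19e-06), GABA receptors (1.97e-05), markers of immature granule neurons (0.000656), neurotrophins and neuropeptides (0.00129), markers of astrocytes (0.0192), hilar mossy cells (0.0233) and endothelial cells and pericytes (0.0248), and calcium signalling genes (0.0416). In the first 3 of these, 1 of 16, 1 of 12 and 1 of 24 members passed over all genes. The lists were not tested without these members, so the p-values do not show a change across each list. Voltage-gated calcium channel genes, 22 measured, had 9 higher and 13 lower members, 0 past the threshold over all genes and a camera adjusted p of 0.654. Neither potassium and HCN channels (adjusted p 0.606) nor glutamate receptors (adjusted p 0.654, ranked higher although their median and mean were -0.00689 and -0.000318) were called, and among GABA receptors (adjusted p 0.265) Gabra2 rose, while Gabra3 differed by 0.36 (SE 0.063, adjusted p 0.0854). Markers of neural stem cells and progenitors (adjusted p 0.542) and of proliferation (adjusted p 0.069) were not called, nor were those of immature granule neurons (adjusted p 0.265), of which the neuronal tubulin gene Tubb3 rose by 0.31 (SE 0.0446). Astrocyte markers were not called (adjusted p 0.307), with the connexin gene Gjb6 rising by 0.38 (SE 0.0481). Endothelial and pericyte markers (adjusted p 0.111) included the fall of Cldn5, and CA3 pyramidal neuron markers (adjusted p 0.528) that of Bok. Markers of tissue outside the dentate gyrus were not called by camera: the lists for neocortex and for thalamus and habenula had adjusted p-values of 0.0806 in both cases, and choroid plexus 0.265. The neocortex list mean was nevertheless higher in every Cav3.1 KO array than in any WT array, at 7.28 ± 0.0957 against 7.15 ± 0.0307 (SD, n = 4, exact permutation p 0.0286). Of its members Ccn2 rose, and Nptx1 fell adjusted over the list alone (-0.31, SE 0.0685). By fry the adjusted p was 3.46e-07 for a change in either direction and 0.261 for a change one way. Without Ccn2 the mean differed by 0.0725 (SE 0.0571, exact permutation p 0.171). Among 7 measured transcripts known to vary between inbred strains, 2 rose, Gabra2 and Nnt (0.52, SE 0.0599, adjusted p 0.017), a mitochondrial transhydrogenase gene, and the call of Nnt was lost without WT replicate 3 (0.0782), WT replicate 4 (0.0823) or Cav3.1 KO replicate 4 (0.0593). That list was not called by camera (adjusted p 0.123), with a mean of 0.189 and a median of -0.011. By fry it was called both for a change one way, higher in Cav3.1 KO (adjusted p 0.02), and for a change in either direction (1.46e-05).

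Genes near Cacna1g were tested separately, because a targeted allele carries linked alleles of the strain in which it was made. On chromosome 11, 371 probes within 10 Mb of Cacna1g were tested and 0 were called by limma, against 56 of 18270 elsewhere (Fisher's exact test, two-sided, p 0.631). Before adjustment, 30 of the 371 had a p under 0.05, which is 8.09% against 8.10% of the other probes, and with array weights 1 was called. The lowest adjusted p among them was 0.082, for the Mediator subunit gene Med1 at -0.19 (SE 0.0325), and the largest difference was 0.46 (SE 0.117, adjusted p 0.248), for the huntingtin-associated protein gene Hap1.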

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

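The tests of vascular cells, of handling and of the neighbours of Nnt, Gabra2 and Ccl21d were chosen after the results were seen, as was the restriction of neighbours to the assembled chromosomes, and the others before. Chance flags about 1 in 20 groups of 4, and 10 of the 140 groups checked held a sample far from the other 3.

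Of these 10, 5 were WT replicate 2. It read 8.625 for Nfkbia, where the other WT arrays lay between 8.794 and 8.804, and 7.272 for Ctla2b, where they lay between 7.548 and 7.6. Its list means were 9.352 for heat shock and unfolded protein response genes (others 9.126 to 9.162), 10.96 for cytosolic ribosomal proteins (others 11.24 to 11.27) and 7.509 for endothelial cells and pericytes (others 7.603 to 7.611). WT replicate 1 read 9.337 for Bok, above 9.166 to 9.19, and its striatum list mean was 6.997, above 6.71 to 6.743. WT replicate 3 read 7.457 for Thbs4, above 7.357 to 7.373. The neocortex list mean was 7.422 on Cav3.1 KO replicate 1, above 7.216 to 7.247, and the mean of calcium and calmodulin-dependent signalling genes was 8.753 on Cav3.1 KO replicate 4, above 8.659 to 8.669.

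Of the 35 splits of the 8 arrays into 4 and 4, only the real one called as many as 61 probes. The highest of the others called 6. This argues against chance, but ranking first of 35 allows no exact permutation p below 0.0286. The other splits also mix the groups, which adds any group difference to their spread and lowers their calls. The ranking does not tell genotype from anything else that divided the groups, such as array order. The number of lists does not argue against chance: 13 of the 35 splits called as many as 8 lists. The highest of the others called 16. For the glucocorticoid-responsive list alone, 1 of the 35 splits, the real one, gave a camera p as small as 8.38e-19. The smallest of the others was 1.33e-07. This argues against chance within the same limit, and the list was 1 of 40 tested, of which 4 reached the smallest exact permutation p. The ranking alone therefore does not exclude chance.

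The first pattern is the rise of glucocorticoid-responsive genes in Cav3.1 KO, with immediate early genes also ranked higher by camera, a call lost with an estimated correlation (adjusted p = 0.169 with an estimated correlation). A contrast of evening against morning clock genes differed by 0.0174 (95% interval -0.0611 to 0.0959), which argues against a large difference along that contrast. A single contrast can take the same value at different phases, so a different clock phase at collection was not excluded. Endothelial and pericyte markers differed by -0.0657 (95% interval -0.159 to 0.0278), well below the 0.37 of the glucocorticoid list, which argues against more vascular cells. These markers went both ways, with 8 of 24 higher and 16 lower, and the fall of Cldn5 weighed on their mean. Their median difference was -0.0181, against 0.153 for the glucocorticoid list. The immediate early list mean was also higher, by 0.183 (95% interval 0.0747 to 0.292), so a difference in handling before collection cannot be told apart from genotype, because no handling record is given in the sources used here. An effect of the missing channel on hormone or stress signalling stays open as a hypothesis. These arrays do not separate it from handling, from array order or from a difference in clock phase that the contrast missed.

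The second pattern is the rise of Nnt and Gabra2, transcripts known to be low in C57BL/6J because of variants of that substrain. Nnt was 6.35 ± 0.0659 (SD, n = 4) in WT and 6.87 ± 0.113 (SD, n = 4) in Cav3.1 KO, although the labels give C57BL/6J for both groups, and the other 5 measured strain-variable genes did not pass. Of 16 genes within 1 Mb of either, 0 were called by limma and 2 had an unadjusted p under 0.05 (12.5%, against a median of 7.69% for random pairs of genes), too few to decide whether donor segments surround them. Around all called genes, 9.3% of neighbours had a p under 0.05, at percentile 97.3 of random sets with a median of 7.8%, which is consistent with linked donor alleles at some called genes, but neighbours may also be co-regulated. Another genetic background at these loci in the Cav3.1 KO samples is therefore a candidate explanation that stays open beside an effect of the missing channel.

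The third pattern is the fall of 3 transcripts placed on chromosome 4, which had the 3 smallest p-values of all probes: Ccl21d, which fell by 1.03 (SE 0.0399), and the predicted genes Gm7819 and Gm1987, named after their values were seen, which fell by 2.70 (SE 0.0941) and 1.38 (SE 0.0455). The 16 tested genes above the median level within 1 Mb of Ccl21d had a median difference of 0.0392 (SD 0.149), from -0.49 for Ccl19 (adjusted p 0.324) to 0.161 for Ccl27a, which argues against a loss of that whole segment. The other 5 probes placed within 1 Mb of Gm1987 had a median difference of -0.0166, which would argue against a segment-wide difference there too. That test decides nothing, because 0 of the 5 lay on the assembled part of the chromosome above the median level, and positions on unplaced pieces do not show which genes are linked. A difference in copy number or allele limited to these transcripts and their near-identical copies thus stays open, as does an effect of genotype.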

How the results depend on the processing

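The normexp offset of 10, the retention of probes with a flagged spot and the removal of Cav3.1 KO replicates 2 and 3 together were chosen after the data were seen. The difference of Cacna1g stayed negative and short of the threshold under all 24 alternatives, and the comparison of the chromosome 11 neighbours kept its result under all 24. The number of called probes, 61 in the main setting, was within 1.5 times of that under 12 of 25 alternatives, from 41 with blank spots subtracted to 87 with an offset of 10. It was 31 with the value table of the series and 124 with array weights, where the cause was not tested, and 123 at the looser adjusted p under 0.10. It was 7 in the first array run, 17 without Cav3.1 KO replicates 2 and 3 and 11 by Student's test without moderation. Fewer arrays or no pooling of the spread leave less power, but whether power alone lowered these counts was not tested. Leaving out each array in turn gave from 16 (without WT replicate 4) to 49 calls, with 26 without WT replicate 3, 29 without Cav3.1 KO replicate 2, 33 without Cav3.1 KO replicate 3, 34 without Cav3.1 KO replicate 4 and 37 without WT replicate 1. The number of called lists, 8 in the main setting, was 15 with arrays scaled to 1 median, where the cause was not tested, 1 by camera with an estimated correlation and by fry, which does not compare a list with other genes, 4 for a change one way and 14 for either direction. It ranged from 6 to 10 when arrays were left out. The glucocorticoid-responsive list passed under all 25 alternatives, at adjusted p-values up to 0.00287. For the 24 named genes, 405 of 576 values kept their direction and the threshold, 171 kept the direction but missed the threshold, and 0 changed direction. Leaving out arrays or adding a block could not change a direction, because these genes were chosen for no overlap and the blocks were balanced. Ccl21d, Fam177a2 and Rasl10a, 3 of the 24, passed under every alternative. Cacna1i, close to the blank level, was 0.0151 with arrays scaled to 1 median (adjusted p 0.983), against -0.02 in the main setting; the cause was not tested. Without Cav3.1 KO replicates 2 and 3 it was 0.00343 (adjusted p 0.998), and Cacna1h was 0.0346 (adjusted p 0.975, against -0.07); the cause was not tested.

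With the replicate number as a block, 8 probes were called. The numbers do not pair the samples: the deviations of same-numbered samples correlated at -0.115, -0.0767, -0.0754 and 0.0109, and no WT sample correlated best with its own number. The 2 later arrays correlated at 0.404, and 3 probes differed between the array runs after adjustment, while 1848 had an unadjusted p under 0.05, where 1057.5 would be expected by chance. Signal over background limits dim genes, whose log2 differences grow when the blank level is subtracted.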

Other observations

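Several transcripts of neuropeptides and growth factors in the dentate gyrus had differences that fell short of the threshold over all genes. In the list of neurotrophins and neuropeptides, 26 members were measured, 12 higher and 14 lower, 0 passed over all genes by limma, and adjusted over the list alone 1 rose and 4 fell (camera adjusted p 0.814, ranked lower, with a median of -0.0124 and a mean of 0.0338, and a fry adjusted p of 0.00129 for a change in either direction). Neuropeptide Y (Npy) differed by -0.40 (SE 0.0787, adjusted p over all genes 0.13), cortistatin (Cort) by -0.42 (SE 0.0925), Vegfa by -0.13 (SE 0.0305) and Bdnf by -0.51 (SE 0.12).

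Markers of thalamus and habenula were high on Cav3.1 KO replicates 2 and 3. The list mean was 7.45 and 7.445 on these arrays, and on the other 6 it ran from 6.639 on WT replicate 4 to 7.148 on WT replicate 2. Over each group it was 6.91 ± 0.263 (SD, n = 4) in WT and 7.13 ± 0.371 (SD, n = 4) in Cav3.1 KO (exact permutation p 0.343). Tac2 was 6.37 ± 0.147 in WT and 7.49 ± 1.42 in Cav3.1 KO (SD, n = 4), and Slc17a6, the vesicular glutamate transporter of these regions, 8.20 ± 0.415 and 9.15 ± 0.56 (SD, n = 4), neither past the threshold. Tac2 read 8.818 and 8.629 on Cav3.1 KO replicates 2 and 3 against 6.254 and 6.27 on replicates 1 and 4, and the nicotinic receptor gene Chrna3 6.224 and 6.173 against 5.787 and 5.817. Slc17a6 was also highest on replicates 2 and 3, at 9.526 and 9.728. Mature granule neuron markers did not follow this division, with list means of 6.938 and 6.907 on replicates 2 and 3 and 6.892 and 7.001 on replicates 1 and 4. Ependymal markers did, at 6.766 and 6.804 against 6.277 and 6.162. Choroid plexus list means were 7.854 and 7.504 against 7.099 and 6.162. In WT they ran from 6.672 on replicate 3 to 7.979 on replicate 2. They were lowest on the 2 later arrays, so uneven tissue content was not confined to Cav3.1 KO replicates 2 and 3.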
